A study of Mus musculus with 3 samples.

How the data were processed

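RNA sequencing was done on total RNA from mouse pro-B cells, 2 Pax5-/- samples and 1 wild-type sample, grouped by the genotype in the labels' titles. The deposited values are gene counts that the authors made with featureCounts against the mm10 genome build, per the submitters' processing notes; the version, the aligner, the gene annotation and the strand setting are not given in the sources used here. Per the file headers, each file lists an Entrez gene number, a gene length in bases, which was not used as a measurement, and a count; the counts are whole numbers and were not normalized. A table of the whole series held the same counts in all 27179 genes for each library. Per the labels' protocols, cells were expanded on OP9 stroma and RNA was isolated with RNeasy Plus columns; day 7 and the depletion of IgM+ cells are stated for both Pax5-/- samples and not for the wild type. Without a stated strand setting, reads of overlapping and antisense genes cannot be separated. Genes with processed pseudogenes or near-identical copies are uncertain: Gapdh had 129, 104 and 157 counts in Pax5-/- samples 1 and 2 and the wild type and Pgk1 had 5, 7 and 13 counts, low for glycolysis genes that every cell uses.

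Symbols and mm10 coordinates were taken from RefSeq genes of GRCm38.p6, the assembly that mm10 names, by Entrez number; 25275 of 27179 numbers (93.0%) matched and 1904 did not. Unmatched numbers held 0.950%, 0.913% and 0.982% of the counts in Pax5-/- samples 1 and 2 and the wild type and stayed in the tests. Library totals were 6487846, 6697879 and 6530057 counts, with 14134, 14306 and 14420 genes above 0. At this depth, 3 counts, the limit that a count of 0 allows, correspond to 0.463, 0.441 and 0.468 TMM-scaled CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

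Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (minimum count 10), libraries were scaled by TMM (factors 1.00, 1.018 and 0.983), and Pax5-/- was compared with wild type by glmQLFit and glmQLFTest with Benjamini-Hochberg adjustment and a threshold of 0.05. With 3 samples in 2 groups there is 1 residual degree of freedom per gene, moderated across genes with 3.15 prior degrees of freedom; the common dispersion was 0.0410, a biological coefficient of variation of 0.203. Log2 fold changes are Pax5-/- over wild type, and their SE is the size of the coefficient over the square root of the quasi-likelihood F. CPM are TMM-scaled. Where a group had no counts, a fold is a lower bound computed with 3 counts over the group, and where it had 1 to 3 counts, a ratio of pooled CPM with an exact Clopper-Pearson 95% interval is given. Log2 CPM for correlations, gene lists and the count of genes with a fold of 2 used a prior count of 2.

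The 24 gene lists were fixed before the data were examined, from general knowledge of B-cell biology: Pax5-activated and Pax5-repressed genes, the early B-lineage programme, V(D)J recombination and end joining, B-cell receptor signalling, MHC class II presentation, light chain and later B cell, plasma cell, T-cell lineage, Notch pathway, NK and innate lymphoid, myeloid, dendritic, erythroid with megakaryocyte and mast, stromal, chemokine receptors and adhesion, chromosome architecture, IL-7 and STAT5 response, glycolysis, cell cycle, immediate early and stress, interferon response, Y-linked, and X inactivation and escape. Of their 374 distinct members, 302 were tested. Each list was tested with camera (limma 3.58.1, preset correlation 0.01) with adjustment over the 24 lists, and 11 lists passed. With an estimated correlation 0 passed, and the smallest camera adjusted p was 0.552. That correlation is estimated with 1 residual degree of freedom, so this setting can decide neither for nor against a list. A list's median was ranked among 10000 random lists of the same size matched on mean expression. This rank, a percentile, does not single out the Pax5 lists. Among lists that did not pass camera it was 0 for early B-lineage, 0.13 for plasma cell and 0.18 for glycolysis. It was 99.4 for Notch and for chemokine receptors and adhesion, and 99.9 for dendritic. The other lists that did not pass ranked from 2.59 to 97.2. Tcfec and Hbb-bt were not analysed here. The rule for named genes, also fixed before, took Pax5, the Y-linked genes and Xist; the 8 genes with the largest and the 8 with the smallest fold change among called genes with a mean CPM of at least 5 and both Pax5-/- samples on the same side, leaving out receptor segments, predicted genes and RIKEN clones; up to 4 called members of each list with a mean CPM of at least 1, by size of the log2 fold change, or the 2 with the smallest p in a list with none; and a fixed set of 16 genes of the B lineage and of Pax5 repression. The result of 1 gene that this rule names is not reported here. Other genes named were chosen after their values were seen.

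The test was run on simulated data for this comparison, in 5 simulations with 200 changed genes each among the real genes. On average 11511 genes were tested. Of genes changed 2-fold 22.2% were recovered, of those changed 4-fold 86.9% and of those changed 8-fold 97.8%, and 7.02% of calls were false. All 3 simulated libraries, the wild type included, had the dispersion trend estimated from the data, with no further spread per gene. The rates therefore take for granted that the wild type varies like the Pax5-/- samples. They also hold for far fewer changed genes than the 2130 called in the data. Alternatives were RLE, library size and upper quartile scaling, no filter or a CPM of at least 1 in at least 2 samples, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, robust dispersion estimation, glmTreat against a fold of 2, a threshold of 0.01, removal of receptor segments, and each Pax5-/- sample left out. Added after seeing the data were the newer quasi-likelihood method of edgeR, removal of X and Y genes, and an assumed coefficient of variation of 0.4. Sequence shared between genes was measured with 50-base stretches of the longest coding GENCODE M21 transcript, in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.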

Results

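Gene expression was measured by RNA sequencing in mouse pro-B cells, the B-lineage precursors that rearrange the immunoglobulin heavy chain, with and without Pax5, a transcription factor of the B lineage. There were 2 Pax5-/- samples and 1 wild-type sample, all from C57BL/6 bone marrow, and the labels describe the Pax5-/- samples as independently prepared. B220+ cells (B220 is a surface form of CD45 on B-lineage cells) were grown on OP9 cells, a stromal feeder line. The labels state an IgM- fraction taken by immunomagnetic depletion at day 7 for both Pax5-/- samples, while the protocol given for the wild type names neither a day nor a depletion. The deposited gene counts summed to 6487846 and 6697879 in Pax5-/- samples 1 and 2 and to 6530057 in the wild type. The comparison asks which genes differ in expression when Pax5 is missing.

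The targeted gene itself was counted in every sample. Pax5 (Entrez 18507; chromosome 4, 44524748 to 44710694, mm10) had 417 and 551 counts in the Pax5-/- samples and 1601 in the wild type, or 72.6 ± 11.7 CPM (library-scaled counts; SD, n = 2) against 250 CPM. It fell by 1.78 on the log2 scale (SE 0.19, adjusted p = 0.0107, edgeR quasi-likelihood test). The labels do not say which exons the allele lacks, and gene-level counts include exons outside a deleted part. The remaining counts check nothing by themselves. The call was lost when a biological coefficient of variation of 0.4 was assumed for every gene.

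The sex labels, male for both Pax5-/- samples and female for the wild type, were matched by the sex-linked genes. All 4 tested Y-linked genes were called higher in Pax5-/- (4 higher when adjusted over the list alone). Camera gave the list an adjusted p of 0.000146 (adjusted p = 0.552 with an estimated correlation). Kdm5d, Eif2s3y and Uty had no counts in the wild type and were at least 124-fold, 98.9-fold and 94.3-fold higher. Ddx3y, with 1 count in the wild type, had a ratio of 498 (95% counting interval 89.2 to 19687). Xist, the RNA that silences the inactive X chromosome, had 1 and 0 counts in Pax5-/- and 1276 in the wild type. The ratio was 2645 in favour of the wild type (95% counting interval 474 to 104530). Of 6 tested genes of X inactivation and escape, 2 fell and 4 were not called (4 lower when adjusted over the list alone). Camera gave an adjusted p of 0.0084 (adjusted p = 0.552 with an estimated correlation). Beside Xist, Kdm6a fell at a log2 fold change of -0.83 (SE 0.15, adjusted p = 0.0346), a call lost in the likelihood ratio test. Sex and genotype were fully confounded in these samples, so no gene's difference can be assigned to the one or the other from the design.

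Of 11783 genes tested, 2130 (18.1%) were called different between Pax5-/- and wild type, 1123 higher and 1007 lower in Pax5-/- (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). A fold of 2 or more in both Pax5-/- samples was found for 2272 genes, 1291 higher and 981 lower, of which 1622 were also called. The median log2 fold change of called genes with counts in both groups was 1.78 in size, with a median SE of 0.21. The spread came from the 2 Pax5-/- samples alone, with 1 residual degree of freedom per gene, and the lone wild type was assumed to vary like them. The count of calls fell to 1206 when a biological coefficient of variation of 0.4 was assumed.

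**Figure D1:**
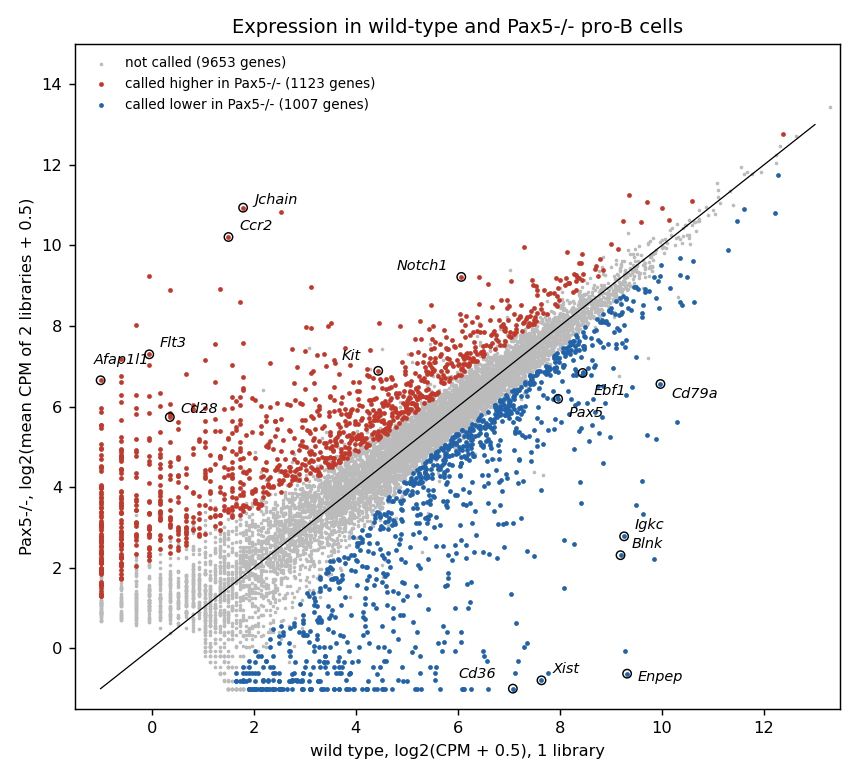
Expression of the 11783 tested genes in the wild-type library (x axis, log2 of CPM plus 0.5) against the mean of the 2 Pax5-/- libraries (y axis, same unit). Each point is a gene, red where called higher in Pax5-/- (1123), blue where called lower (1007) and grey otherwise, the line marks equal expression, and circled genes are named in the text, with Jchain and Ccr2 far above the line and Enpep and Blnk far below it.

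The 8 genes with the smallest fitted fold changes, receptor segments such as Iglc1 and predicted genes left out, had 0 to 2 counts over both Pax5-/- samples. Enpep, the gene of the pre-B-cell surface aminopeptidase BP-1, had 2 counts over both Pax5-/- samples and 4090 in the wild type, a ratio of 4238 (95% counting interval 1173 to 35008). Cd36, a fatty acid scavenger receptor, was at 0 in both and at least 597-fold lower. Ms4a1, which encodes CD20, was at least 305-fold lower, Lgr5 at least 303-fold, Slamf6 at least 301-fold, Grb7 at least 220-fold and Polm, a DNA polymerase of end joining, at least 170-fold. Xist was also among the 8. Of the 8 genes with the largest fitted fold changes, 3 were the Y-linked Kdm5d, Eif2s3y and Uty. The other 5 had no counts in the wild type: Afap1l1 was at least 214-fold higher, Apobr at least 132-fold, Crisp1 at least 98.4-fold, Creb5 at least 70.9-fold and Slc5a9 at least 66.6-fold. The call of Crisp1 was lost with limma-voom.

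Genes that Pax5 is known to activate in the B lineage were lower together. Of 27 tested members of this list, which was drawn from general knowledge of Pax5 targets, 23 fell, 0 rose and 4 were not called (24 lower when adjusted over the list alone). Their median log2 fold change was -3.92, lower than all of 10000 random lists matched on expression. The camera test gave an adjusted p of 7.7e-13 (adjusted p = 0.552 with an estimated correlation). Blnk, the adaptor downstream of the pre-B-cell receptor, stood at 4.47 ± 1.54 CPM (SD, n = 2) in Pax5-/- against 584 CPM in the wild type (log2 fold change -7.03, SE 0.30). Cd79a, a signalling chain of that receptor, was at 93.9 ± 20.9 against 1004 CPM (log2 fold change -3.42, SE 0.21). Siglecg had a log2 fold change of -8.83 (SE 0.61), a call lost with DESeq2, and Cd55 was at 0 in Pax5-/-, at least 53.9-fold lower. Mycn, Nr3c1, Txnip and Cnr2 were the 4 not called.

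Genes that Pax5 is known to repress in B cells, many of them typical of myeloid or T cells, moved the other way. Of 17 tested members, 11 rose, 1 fell and 5 were not called (13 higher and 2 lower when adjusted over the list alone). The median log2 fold change was 3.54, higher than all of 10000 matched random lists. The camera test gave an adjusted p of 5.93e-05 (adjusted p = 0.552 with an estimated correlation). Jchain, the joining chain of secreted IgM and IgA, rose from 2.96 CPM to 1960 ± 155 CPM (SD, n = 2; log2 fold change 9.36, SE 0.19, adjusted p = 0.00234). Ccr2, a chemokine receptor of monocytes, rose from 2.34 to 1183 ± 105 CPM (log2 fold change 8.97, SE 0.21). Flt3, a cytokine receptor of early progenitors, had 3 counts in the wild type and a ratio of 335 (95% counting interval 114 to 1626), and Cd33, with 1 count there, a ratio of 439 (78.6 to 17362). Notch1 rose from 66.6 to 595 ± 77.5 CPM (log2 fold change 3.16, SE 0.18, adjusted p = 0.00413). Cd28, a T-cell costimulatory receptor, rose from 0.78 to 52.9 ± 23.1 CPM (log2 fold change 6.05, SE 0.72, adjusted p = 0.0140), a call lost with limma-voom. The member that fell was Atp1b1, a sodium pump subunit, at -5.99. Csf1r, the macrophage colony-stimulating factor receptor, was not called, with 8, 4 and 22 counts and a log2 fold change of -1.90 (SE 0.63, adjusted p = 0.116). Nor was Ccl3, with 1 count in the wild type and a ratio of 18.8 (95% counting interval 3.18 to 762; adjusted p = 0.0552). Ccl3 passed the threshold with RLE scaling, both other filters, robust dispersion estimation and the likelihood ratio test, and Csf1r with the likelihood ratio test only.

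**Figure D2:**
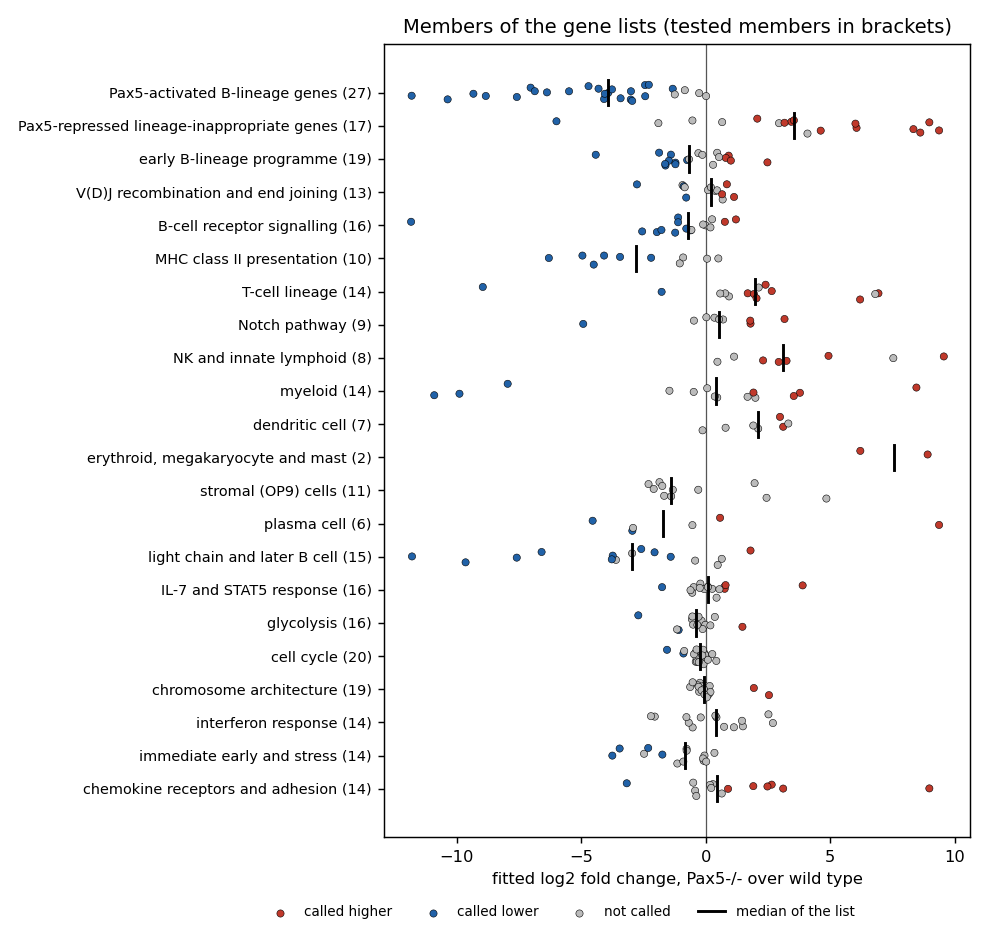
Fitted log2 fold change of Pax5-/- over wild type (x axis) for the tested members of 22 gene lists (rows, with the number of tested members in brackets). Each point is a gene, red where called higher, blue where called lower and grey where not called, and black bars are list medians, -3.92 for Pax5-activated and 3.54 for Pax5-repressed genes; values of genes with no counts in a group depend on the prior count.

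The early B-lineage programme was divided. Of 19 tested members, 4 rose, 9 fell and 6 were not called (7 higher and 10 lower when adjusted over the list alone; median log2 fold change -0.67, camera adjusted p = 0.173). That median lay below every matched random list, as for the Pax5-activated genes, although camera did not call the list. Vpreb3 fell by 4.41 on the log2 scale (SE 0.46), Cd79b by 1.87 (SE 0.10) and Tcf3, which encodes E2A, by 1.63 (SE 0.12). Ebf1, a factor that acts with E2A in B-lineage commitment, fell by 1.62 (SE 0.16). Vpreb1, a surrogate light chain, fell by 1.22 (SE 0.22, adjusted p = 0.0352). Kit, the stem cell factor receptor, rose from 21.2 to 118 ± 0.83 CPM (SD, n = 2; log2 fold change 2.47, SE 0.16). Il7r, the interleukin-7 receptor, rose from 237 to 448 ± 37.5 CPM (log2 fold change 0.92, SE 0.13, adjusted p = 0.0220). Igll1 was not called, with a log2 fold change of -0.67 (SE 0.15, adjusted p = 0.0556), nor was Ikzf1, at 0.29 (SE 0.10, adjusted p = 0.123). The call of Vpreb1 was lost when library size alone was used for scaling and that of Vpreb3 with robust dispersion estimation. Igll1 passed the threshold with RLE scaling, both other filters, DESeq2 and robust dispersion estimation.

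Among 13 tested genes of V(D)J recombination and end joining, 3 rose, 3 fell and 7 were not called (4 higher and 5 lower when adjusted over the list alone). The median log2 fold change was 0.21, the mean -0.14 and the camera adjusted p 0.81. Dntt, which adds nucleotides at junctions, rose by a log2 fold change of 1.14 (SE 0.17) and Rag1, a subunit of the recombinase, by 0.85 (SE 0.15, adjusted p = 0.0313), a call lost in the likelihood ratio test. Lig4, the end-joining ligase, fell by 2.76 on the log2 scale (SE 0.23) and Hmgb1 by 0.89 (SE 0.12). Hmgb1 is uncertain because it shares sequence with processed copies.

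Most, not all, tested genes of B-cell receptor signalling and of antigen presentation by MHC class II were called lower. Of 16 tested signalling genes, 9 fell, 2 rose and 5 were not called (10 lower and 2 higher when adjusted over the list alone). Their median log2 fold change was -0.69 and the camera adjusted p 0.0223 (adjusted p = 0.552 with an estimated correlation). Beside Ms4a1, these included Cd22, an inhibitory receptor, at -2.55 (SE 0.51), Bank1 at -1.96 (SE 0.36) and Pik3ap1 at -1.78 (SE 0.16). The call of Cd22 was lost with DESeq2, with library size alone and with robust dispersion estimation, and that of Bank1 with DESeq2. Of 10 MHC class II genes, 6 fell, 0 rose and 4 were not called (6 lower when adjusted over the list alone). The list had a median log2 fold change of -2.82 and a camera adjusted p of 0.000738 (adjusted p = 0.552 with an estimated correlation). H2-Ab1 was at 0.827 ± 0.0775 CPM (SD, n = 2) against 66.4 CPM (log2 fold change -6.29, SE 0.23). H2-Aa was at -4.95 (SE 0.58), H2-Eb1 at -4.49 (SE 0.31) and Ciita, the transactivator of these genes, at -4.08 (SE 0.46). Because no IgM depletion is stated for the wild type, the differences in both lists cannot be assigned to Pax5 alone.

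Light-chain transcripts were also lower in Pax5-/-, as were some genes of later B cells. Of 15 tested members, 9 fell, 1 rose and 5 were not called (10 lower and 1 higher when adjusted over the list alone). Their median log2 fold change was -2.95 (by log2 CPM -2.09 in Pax5-/- sample 1 and -3.17 in sample 2) and the camera adjusted p 0.00105 (adjusted p = 0.552 with an estimated correlation). Igkc, the kappa constant gene, was at 6.37 ± 2.78 CPM (SD, n = 2) in Pax5-/- and 613 CPM in the wild type (log2 fold change -6.59, SE 0.38, adjusted p = 0.00404). The wild type is the sample whose protocol names no IgM depletion. Iglc3 was at -7.58 (SE 0.27), and Iglc1 and Iglc2 were at 0 in Pax5-/-, at least 298-fold and at least 67.0-fold lower. Sequence shared between these lambda constant genes was not measured here, so reads split between them are uncertain. Of the 9 members that are not immunoglobulin genes, 3 fell, 1 rose and 5 were not called. The member that rose was Il2ra, at a log2 fold change of 1.80. Of 6 plasma cell genes, 2 rose, 2 fell and 2 were not called (2 higher and 3 lower when adjusted over the list alone). The median was -1.73 and the camera adjusted p 0.509. Sdc1, which encodes the plasma cell marker CD138, fell by 4.54 on the log2 scale (SE 0.35) and Ell2 by 2.95 (SE 0.41). Jchain and Mzb1 rose, Mzb1 by a log2 fold change of 0.57 (SE 0.11), a call lost in the likelihood ratio test.

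T-cell, Notch and innate lymphoid genes were higher in part. Of 14 tested T-cell genes, 7 rose, 2 fell and 5 were not called (8 higher and 2 lower when adjusted over the list alone). Their median was 1.99 and the camera adjusted p 0.00717 (adjusted p = 0.552 with an estimated correlation). Cd27 had 3 counts in the wild type and a ratio of 76.2 (95% counting interval 25.9 to 371). Cd247, the zeta chain of the T-cell receptor complex, had 1 count there and a ratio of 138 (24.5 to 5450). Cd5 rose by a log2 fold change of 2.65 (SE 0.48), and Tcf7, which encodes TCF1, by 1.68 (SE 0.28). Cd2 fell, with 1 count over both Pax5-/- samples against 298 (ratio 618, 95% counting interval 110 to 24475). Bcl11b, with 0, 0 and 1 counts, and Cd3e, with 0, 1 and 0, were below the filter. So were Cd3d (1, 0 and 2), Cd3g (0, 0 and 2), Cd4 (3, 2 and 7), Cd8a (1, 1 and 0) and Cd8b1 (1, 2 and 1). The list had 21 members, and its median and camera p cover only those that passed the filter.

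Of 9 Notch pathway genes, 3 rose, 1 fell and 5 were not called (3 higher and 2 lower when adjusted over the list alone; median log2 fold change 0.54, camera adjusted p = 0.263). Notch2 (1.79, SE 0.18) and Il2ra (1.80, SE 0.20) rose beside Notch1. Dtx1, a known target of Notch signalling, fell by 4.92 on the log2 scale (SE 0.39). Of 8 NK and innate lymphoid genes, 5 rose, 0 fell and 3 were not called (6 higher when adjusted over the list alone). Their median was 3.08, or 2.91 with genes at 0 set to their bound. The camera test gave an adjusted p of 0.00428 (adjusted p = 0.552 with an estimated correlation). Nkg7 rose by 4.92 (SE 0.63), Klrd1 by 3.24 (SE 0.43) and Cd7 by 2.93 (SE 0.34). Zbtb16, which encodes PLZF, had no counts in the wild type and was at least 30.7-fold higher. Other members of this list of 17 were below the filter. Among them, Ncr1 and Eomes each had 0, 0 and 1 counts in Pax5-/- samples 1 and 2 and the wild type. Tbx21 had 0, 0 and 0 and Prf1 1, 0 and 8. The list median covers only the members that passed the filter. The calls of Cd247, Cd5, Nkg7 and Zbtb16 were lost with limma-voom.

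Markers of other cell types that a culture could hold moved both ways. Of 14 myeloid genes, 4 rose, 3 fell and 7 were not called (5 higher and 3 lower when adjusted over the list alone). The median log2 fold change was 0.41 (by log2 CPM 0.03 in Pax5-/- sample 1 and 0.59 in sample 2), the mean -0.60 and the camera adjusted p 0.794. Neutrophil genes went both ways: S100a9, Ngp and S100a8 had 232, 115 and 30 counts in the wild type and 0 in Pax5-/-. They were at least 160-fold, 79.4-fold and 20.7-fold lower, whereas the granule protease genes Ctsg and Prtn3 rose by log2 fold changes of 3.78 (SE 0.38) and 3.53 (SE 0.33). Mpo and Ltf were not called. Cx3cr1 was at 0 in the wild type and at least 14.2-fold higher. Of 7 dendritic cell genes, 2 rose and 5 were not called (2 higher when adjusted over the list alone). The median log2 fold change was 2.10 and the camera adjusted p 0.0746. That median is the value of Irf7, at 364 and 11.3 CPM in Pax5-/- samples 1 and 2 and 43.7 CPM in the wild type. Bst2, at 787, 126 and 263 CPM, also lay on opposite sides of the wild type in the 2 samples. Ccr9 rose by 3.11 (SE 0.28) and Siglech by 2.98 (SE 0.42), the latter lost with limma-voom. Of the erythroid, megakaryocyte and mast cell genes, only Cpa3 and Mcpt8, both of mast cells and basophils, were tested, and both rose (2 higher when adjusted over the list alone). Their median was 7.55, or 5.24 with Cpa3 at its bound, and the camera adjusted p 0.0150 (adjusted p = 0.552 with an estimated correlation). Cpa3 was at least 19.5-fold higher, and Mcpt8 had 1 count in the wild type and a ratio of 82.5 (95% counting interval 14.6 to 3278). Both passed the filter through the Pax5-/- samples only, so their median and camera p cannot speak for the list of 19. Among its other members, Ms4a2, Fcer1a and Prss34 had 0 counts in each library. Of 11 stromal genes, 0 were called by the edgeR test in either direction (0 when adjusted over the list alone; median log2 fold change -1.39, camera adjusted p = 0.263). Cxcl12 was at -2.30 (SE 0.58, edgeR adjusted p = 0.0693) and Fn1 at -2.09 (SE 0.51, adjusted p = 0.0627), both of which passed the threshold with RLE scaling, no filter, robust dispersion estimation and the likelihood ratio test.

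Chemokine receptor and adhesion genes gave 6 that rose, 1 that fell and 7 not called of 14 (6 higher and 3 lower when adjusted over the list alone; median log2 fold change 0.47, by log2 CPM 0.26 in Pax5-/- sample 1 and 0.56 in sample 2; camera adjusted p = 0.0715). Beside Ccr2 and Ccr9, Cxcr3 rose by 2.65 (SE 0.50), a call lost with DESeq2 and with limma-voom. Cd44, an adhesion receptor for hyaluronan, fell by 3.17 on the log2 scale (SE 0.18). Of 19 genes of chromosome architecture, 2 rose, 0 fell and 17 were not called (2 higher when adjusted over the list alone; median log2 fold change -0.08, camera adjusted p = 0.753). Wapl, which releases cohesin from chromatin, rose from 35.4 to 205 ± 3.03 CPM (SD, n = 2; log2 fold change 2.54, SE 0.15, adjusted p = 0.00415). Satb1, a chromatin organiser, rose from 45.7 to 174 ± 1.20 CPM (log2 fold change 1.93, SE 0.15, adjusted p = 0.00613).

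Most genes of the IL-7 response, glycolysis and the cell cycle were not called. Of 16 IL-7 and STAT5 response genes, 3 rose, 1 fell and 12 were not called (3 higher and 1 lower when adjusted over the list alone; median log2 fold change 0.09, camera adjusted p = 0.764). Bcl2, an inhibitor of apoptosis, rose from 6.40 to 94.9 ± 49.5 CPM (SD, n = 2; log2 fold change 3.89, SE 0.64). Socs2 rose by 0.80 (SE 0.16) and Jak3 by 0.76 (SE 0.14). Ccnd3, a D-type cyclin, fell by 1.75 on the log2 scale (SE 0.10). The call of Bcl2 was lost with limma-voom and robust dispersion estimation, that of Socs2 with limma-voom, library size alone and the likelihood ratio test, and that of Jak3 with the likelihood ratio test. Of 16 glycolysis genes, 1 rose, 3 fell and 12 were not called (1 higher and 3 lower when adjusted over the list alone; median log2 fold change -0.41, camera adjusted p = 0.0706). Pfkp fell by 2.71 (SE 0.21), Ldha by 1.09 (SE 0.11) and Aldoa by 0.52 (SE 0.11). The glucose transporter gene Slc2a3 rose by 1.47 (SE 0.18). The call of Aldoa was lost with library size alone, upper quartile scaling and the likelihood ratio test. Aldoa is also uncertain because it shares sequence with processed copies. Of 20 cell cycle genes, 2 fell, 0 rose and 18 were not called (2 lower when adjusted over the list alone; median log2 fold change -0.23, by log2 CPM -0.12 in Pax5-/- sample 1 and -0.37 in sample 2; camera adjusted p = 0.0715). These were Rrm2 at -1.55 (SE 0.12) and Ccna2 at -0.90 (SE 0.16).

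Immediate early and stress genes were lower in part, with 4 that fell, 0 that rose and 10 not called of 14 (5 lower when adjusted over the list alone). Their median log2 fold change was -0.84 (by log2 CPM -0.62 in Pax5-/- sample 1 and -1.29 in sample 2) and the camera adjusted p 0.0140 (adjusted p = 0.552 with an estimated correlation). Asns, which makes asparagine, fell by 3.75 on the log2 scale (SE 0.21), Egr1 by 3.46 (SE 0.53), Trib3 by 2.31 (SE 0.24) and Ddit3 by 1.74 (SE 0.27), the last a call lost with DESeq2. None of the 14 interferon-response genes was called by the edgeR test (0 when adjusted over the list alone; median log2 fold change 0.41, mean 0.31, by log2 CPM a median of 1.36 in Pax5-/- sample 1 and -3.72 in sample 2; camera adjusted p = 0.446 in the downward direction). The 2 Pax5-/- samples differed from each other: Isg15 was at 283 and 2.94 CPM in Pax5-/- samples 1 and 2 and 52.1 CPM in the wild type. The 2 with the smallest p were Oasl1, at 23.6, 0 and 53.8 CPM (log2 fold change -2.20, SE 1.59, adjusted p = 0.387), and Ifi44, at 50.5, 0.147 and 104 CPM (log2 fold change -2.05, SE 1.78, adjusted p = 0.466). Both passed the threshold with the assumed coefficient of variation of 0.4, a setting that does not use the spread between the 2 Pax5-/- samples.

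**Figure D3:**
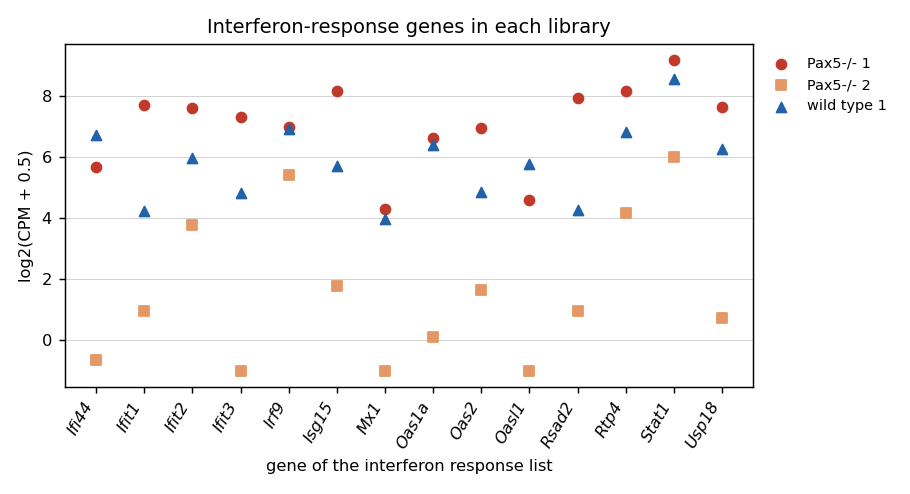
Expression of the 14 interferon-response genes (x axis) in each library, as log2 of CPM plus 0.5 (y axis); circles are Pax5-/- sample 1, squares Pax5-/- sample 2 and triangles the wild type, and each point is 1 library, so there are no error bars. In each gene Pax5-/- sample 2 is the lowest, as for Isg15 at 2.94 CPM against 283 and 52.1 CPM.

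Across genes, log2 CPM of the 2 Pax5-/- samples correlated at Pearson r = 0.972, and each of them correlated less with the wild type (r = 0.827 and 0.813); genes are not independent replicates. The counts of the 2 Pax5-/- samples differed by a chi-square of 16.3 per degree of freedom, which excludes only that the same counts were deposited for both. More than 4-fold differences were found in 138 genes between them and in 1300 and 1383 genes between each of them and the wild type. Immunoglobulin and T-cell receptor segments made up 127 of the tested genes, of which 12 rose and 49 fell, and predicted genes, RIKEN clones and genes without a symbol made up 768, of which 47 rose and 30 fell.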

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

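The assumed coefficient of variation of 0.4, the fit without X and Y genes and the newer quasi-likelihood method were chosen after seeing the data. The count of 2130 called genes ranged from 1851 to 2611 over 3 other scalings, 2 other filters, DESeq2, limma-voom, the likelihood ratio test, robust estimation, the newer method and the removal of receptor segments or of X and Y genes. Higher calls outnumbered lower ones except with limma-voom (901 higher, 1024 lower); the cause was not tested. The filter of a CPM of at least 1 in 2 samples gave 1219 and 862, but it drops genes seen only in the single wild type, by construction: 230 called genes went untested, all lower, among them 21 named genes and the 3 myeloid genes that fell. With it camera called 15 lists, a count this selection shapes. No called gene changed direction, and of the 2130, 1746 were also called by DESeq2 and 1843 by limma-voom. The planned legacy setting is the installed default and gave 2130 again. Against a fold of 2 (glmTreat), 824 genes were called, 456 higher and 368 lower, and at an adjusted p under 0.01, 569, 309 higher and 260 lower; both are stricter by construction. With the assumed coefficient of variation of 0.4, 1206 were called, 623 higher and 583 lower, and the Pax5 log2 fold change of -1.78 had an adjusted p of 0.0819. This setting is about 2 times the estimated 0.203. A fold of 4 or more in both Pax5-/- samples was found for 1123 genes. The correlation of the 2 Pax5-/- samples was 0.984 without a filter; the cause was not tested. Camera called 11 gene lists. With an estimated correlation 0 were called, and the Y-linked list, whose genes match the sex labels, also had a camera adjusted p of 0.552. That correlation rests on 1 residual degree of freedom, so this setting can decide neither for nor against a list. With fry, which tests another hypothesis, 7 were called (5 of the 11 lost and 1 other gained). The cause of the difference from fry was not tested. Of 101 named genes measured, 93 were called, 21 of them lost the call, while still tested, under at least 1 scaling, filter or test listed before the data were examined and 38 when the added ones are included, 27 of these with the assumed coefficient of variation. Of the 8 not called, 7 passed under at least 1 of these settings. None changed sign while called. In the passages on single genes, a call lost with the assumed coefficient of variation is marked for Pax5 only. The call of 1 named gene lost with the newer quasi-likelihood method is not marked there. Leaving out a Pax5-/- sample leaves 1 sample against 1, a value with no test: 2802 genes without sample 1 and 2701 without sample 2 had a fold of 2 or more against the wild type. List medians of a single sample are by log2 CPM, another scale than the fitted medians, and differed in sign between the samples only for the interferon list (1.36 and -3.72). No paired analysis was possible because the labels pair neither Pax5-/- sample with the wild type. No other split of the samples was tested, since neither group has 3 samples. Depth limits genes near the floors of 0.441 to 0.468 CPM, and the single wild-type library limits every comparison.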

Other observations

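The tests in this part were chosen only after the result was seen, except the measurement of sequence shared by Rpl29, Rps3a1 and Hspa8. The genes and lists were also chosen after their values were seen, apart from the interferon, myeloid, dendritic and later B-cell lists. Genes of fetal growth and imprinting differed in both directions. A list of 23 such genes was assembled after Igf2 and H19 had been noticed and includes them. Of its 14 tested members, 8 rose, 1 fell and 5 were not called, with a median log2 fold change of 1.18. That median covers only members that passed the filter. Lin28a, Igf2bp1, Hmga2, Phlda2 and Slc38a4 had 0 counts in each library. Igf2, a fetal growth factor, had 2930 and 5095 counts in the Pax5-/- samples and 3 in the wild type, a ratio of 1291 (95% counting interval 442 to 6260). H19, the imprinted RNA beside it, rose by a log2 fold change of 7.90 (SE 0.80). Lin28b, a regulator of fetal haematopoiesis, and Dlk1 had no counts in the wild type and were at least 17.4-fold and at least 9.97-fold higher. Igf2bp3 rose by 1.77 (SE 0.18). Igf2r, at -1.28, and Cdkn1c, at -2.58, were not called. The labels give no age for the animals.

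Genes of serine synthesis, amino acid transport and the ATF4 response were mostly lower in Pax5-/-. Of 16 tested members of a list made after Asns, Trib3 and Ddit3 had been noticed, and without them, 12 fell, 0 rose and 4 were not called, with a median log2 fold change of -1.04. No p is given, because the genes were chosen after the values were seen. Atf4 fell by 1.70 on the log2 scale (SE 0.14), Mthfd2 by 2.02 (SE 0.18), Psat1 by 1.83 (SE 0.13) and Slc7a5 by 1.59 (SE 0.14). Of 7 T-cell receptor constant genes, 3 rose, 1 fell and 3 were not called: Trdc had 1412, 2045 and 2 counts (ratio 834, 95% counting interval 231 to 6890), Trbc2 910, 832 and 3 and Trbc1 131, 113 and 4. V, D and J segments of Trb summed to 250, 254 and 2 counts and those of Trd to 68, 110 and 1, while Trg segments summed to 99, 174 and 160 and Tra segments to 35, 47 and 22. Ighg2b had 613 counts in the wild type and 0 in Pax5-/-, and Igkv segments summed to 245, 203 and 1613 counts. The Ighv2 and Ighv5 families held 267 of 638 Ighv counts (41.8%) in Pax5-/- sample 1, 162 of 564 (28.7%) in sample 2 and 204 of 1037 (19.7%) in the wild type. The Ighv1 and Ighv8 families held 41.8%, 53.4% and 51.0%. Similar V genes share reads, so these shares are uncertain.

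Interferon-response genes separated the 2 Pax5-/- samples: all 14 were higher in sample 1, with a median log2 ratio of 5.95, and 98 other genes were over 4-fold higher there against 6 in sample 2 (ratios of CPM plus 0.5). RNA of myeloid or dendritic cells in sample 1 is argued against by their tested markers (Irf7 and Bst2, which interferon induces, left out). Their median log2 ratio between the samples was -0.0591 over 19 genes (quartiles -0.757 and 0.121). Of these, 6 were higher in sample 1 and 0 over 4-fold higher there. S100a8, S100a9 and Ngp have a ratio of 0 because both samples had no counts. Markers below the filter are not covered, so a small share of such cells is not excluded. Over all other tested genes the median absolute log2 ratio was 0.176, so most genes were close in the 2 samples after scaling. A difference in composition cannot be decided by it, because CPM are scaled for depth and a median does not see a minority of genes. A difference between the animals or cultures in exposure to interferon stays open, and no biological explanation was tested, since the labels name none. The wild type lay between the 2 samples in most of these genes, and 0 of the 14 were called between genotypes by the edgeR quasi-likelihood test. Oasl1 and Ifi44, in which the wild type was highest, were not called in it either.

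Light-chain and some later B-cell transcripts were higher in the wild type. Reads shared among the lambda constant genes are argued against as the whole cause by Igkc, which has no such copy and was 96.9-fold higher. For the lambda genes themselves Igkc decides nothing. Iglc1 had 0, 0 and 431 counts, Iglc2 0, 0 and 97 and Iglc3 2, 4 and 578. Reads moved among them would not lower all of them together. Cells past the pro-B stage in the wild-type library may contribute, as no depletion of IgM+ cells is stated for it; the list members that are not immunoglobulin genes had a median log2 fold change of -2.59, with 6 of 9 lower in Pax5-/- (3 called) and 3 higher (1 called), so this cannot be told apart from an effect of Pax5 on the cells themselves. The genotype, the sex and any difference in preparation stay open, because there is 1 wild-type library.

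Rpl29, Rps3a1 and Hspa8 were far lower in Pax5-/-, with 29, 26 and 5882 counts for Rpl29, 33, 37 and 769 for Rps3a1 and 314, 330 and 8089 for Hspa8. Their log2 fold changes were -7.78, -4.50 and -4.70. A library-wide difference in how reads shared between gene copies were counted is argued against as the cause of falls this large. The other ribosomal protein genes that share at least 50% of their 50-base stretches had a median log2 fold change of -0.423 over 37 genes (quartiles -0.618 and -0.0945). Of these 0 were called, though some had few counts. Over all 81 other ribosomal protein genes, these included, the median was -0.172, so a small shift of this kind stays open. Rpl29 shared 47.9% of its stretches with other annotated genes, Rps3a1 71.0% and Hspa8 74.8%. A sequence variant between the animals at these genes or their copies could move reads between copies, and cannot be told apart from lower expression, because the reads were not used here.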
